A study of Mus musculus with 2 samples.

How the data were processed

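Whole-exome sequencing was done on genomic DNA of 2 mouse tumour cell lines, the melanoma line B16BL6 and the colon carcinoma line MC38, both from the C57BL/6 strain, with 1 library per line. Per the labels, DNA was isolated on silica columns, exons were enriched with a mouse exome capture pool and 76-nt read pairs were sequenced. The submitters' processing notes name BWA, Picard, GATK and the genome build GRCm38, with no versions. The order of these steps, the caller's settings, the filters on calls and the gene annotation program are not given in the sources used here. A matched normal tissue is not named in the labels, so whether germline differences from the reference were removed is unknown.

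The deposited file of each line is a list of called variants, 1 per line of text, with chromosome, start, end, reference and alternative allele, a genotype call (heterozygous or homozygous), consequence, gene symbol, transcript and coding and protein change. The unit of analysis was therefore 1 called variant. Read depth, allele fraction and call quality are not in the lists, so the depth behind each call is unknown. Only exonic variants are listed, and sites that could not be called cannot be told from sites without a variant. The lists hold 1654 variants of B16BL6 and 3482 of MC38 with no duplicate. A RefSeq transcript was found for 1587 of the 1612 B16BL6 variants with a transcript name and for 3392 of the 3433 MC38 variants. Of these, 1585 and 3383 lay inside the bounds of the same gene in the GRCm38 annotation. Gene symbols were updated from that annotation by transcript.

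The groups, tests, gene lists, rule for naming genes and alternatives were fixed before the data were examined. With 1 library per line, every test compared the lists of calls and not cell types, and intervals cover counting error only. Numbers of variants carried exact Poisson 95% intervals, and their ratio, MC38 over B16BL6, an exact conditional binomial interval and two-sided p. Shares carried exact Clopper-Pearson 95% intervals. Differences between the lines were tested with two-sided Fisher's exact tests and given as conditional odds ratios, MC38 over B16BL6. Benjamini-Hochberg adjustment was made over the 6 base changes, the 12 strand tests, the 6 strand differences, the 20 chromosomes and the 18 gene lists, each family on its own. Tests against gene numbers were adjusted over both lines together, as fixed in the design, over 36 tests for the lists and 40 for the chromosomes. The threshold was 0.05. Protein-altering variants were missense, stop-gained, stop-lost, frameshift and in-frame changes.

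Base changes were written with the pyrimidine of the base pair first. For each change the strand of the altered purine was read from the coding-strand alleles in the coding change, and its share was tested against 50% with an exact binomial test. A comparison with the base composition of coding sequence was planned, but no genome was at hand, so the difference between the lines took its place. Sequence context was left out for the same reason. Coding lengths were also not at hand, so gene lists, chromosomes and the overlap of altered genes were set against numbers of protein-coding genes, without a correction for gene size. The planned allele fraction result was replaced, after the lists were seen, by the share of homozygous calls.

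Up to 25 altered genes of the fixed lists were named per line, truncating changes first and then in alphabetical order, with the 5 genes holding most protein-altering variants in each line and the first 5 genes in genome order with an identical protein-altering variant in both. Alternatives left out variants found in both lines, variants within 10 bp of another, large gene families, or all but 1 variant per gene and line. Others used missense variants only, other definitions of a shared variant, windows of 5 and 50 bp, and gene numbers as the background of chromosomes and gene lists. One further alternative, which left out shared variants and genes with 3 or more of them, was chosen after seeing the data. Alternatives with a minimum depth or allele fraction could not be run. The tests were tested on simulated data made by shuffling variants between the lists and by planting a known strand share. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.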

Results

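The exomes of B16BL6, a subline of the B16 melanoma, and MC38, a colon carcinoma, were each sequenced once. Both tumour lines come from C57BL/6 mice. The data are 1654 variants called against the reference genome in B16BL6 and 3482 in MC38. The read depth is unknown. The question the design allows is how the protein-altering variants and the kinds of base change of these tumour lines differ.

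MC38 carried more variants than B16BL6 in nearly every class. Protein-altering variants numbered 1178 (95% interval 1112 to 1247) in B16BL6 and 2560 (2462 to 2661) in MC38, a ratio of 2.17 (2.03 to 2.33, exact binomial p = 1.22e-115). They fell in 918 genes of B16BL6 and 2062 genes of MC38. Missense variants numbered 1107 and 2327, and synonymous variants 434 and 873. Stop-gained variants differed most, with 30 in B16BL6 and 155 in MC38, a ratio of 5.17 (3.48 to 7.92). Frameshift deletions numbered 19 and 56 (ratio 2.95, 1.72 to 5.25), whereas frameshift insertions numbered 16 and 17. Among variants found in 1 line only the protein-altering counts were 947 and 2329, a ratio of 2.46 (2.28 to 2.66). Callable length per line is unknown, so the counts are not rates per megabase.

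The balance of amino acid-changing to silent changes was not detectably different between the lines. Missense and stop-gained variants numbered 2.62 per synonymous variant in B16BL6 and 2.84 in MC38 (odds ratio 1.08, 0.945 to 1.24, Fisher's exact p = 0.239). Stop-gained changes made up 2.64% of these in B16BL6 and 6.21% in MC38 (odds ratio 2.44, 1.63 to 3.77, Fisher's exact p = 2.69e-06). Of the 154 single-base stop-gained changes in MC38, 111 were C>A, among them Sox10 Y300X, Tyrp1 E338X and Smarca4 E1615X. Of the 30 in B16BL6, 17 were C>T, among them Apc Q1039X, and 7 were C>A. In variants of 1 line only, the ratio to synonymous changes was 3.18 in B16BL6 and 3.11 in MC38, so the direction of that small difference turned. These ratios were not corrected for the kinds of base change, which differed between the lines.

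C>A changes dominated MC38, and B16BL6 had no single dominant change. C>A made up 46.1% of the 3401 single-base variants of MC38 (44.4 to 47.8) and 12.4% of the 1610 of B16BL6 (10.8 to 14.1), an odds ratio of 6.03 (5.12 to 7.13, adjusted Fisher's exact p = 3.09e-132). C>G was also more frequent in MC38, at 13.7% against 10.1% (odds ratio 1.42), and T>A at 11.6% against 8.57% (odds ratio 1.40). The other 3 changes were more frequent in B16BL6. C>T made up 30.9% there and 17.1% in MC38 (odds ratio 0.463), T>C 20.9% and 6.12% (odds ratio 0.246), and T>G 17.1% and 5.35% (odds ratio 0.273). The largest of the 6 adjusted p values was 0.00100. Among variants of 1 line only, C>A reached 50.6% in MC38 and 12.5% in B16BL6, and transitions made up 18.4% and 49.2%.

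**Figure D1:**
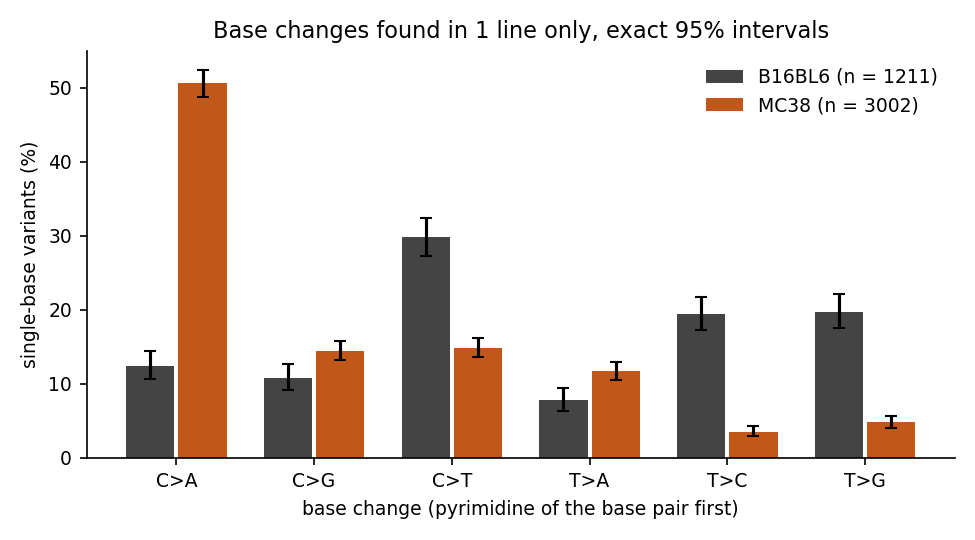
Share of each base change, in percent, among single-base variants found in 1 line only, with exact 95% intervals as bars; grey stands for B16BL6 (n = 1211) and orange for MC38 (n = 3002). C>A stands at 50.6% in MC38 and 12.5% in B16BL6, while T>C and T>G stand at 19.4% and 19.7% in B16BL6 and at 3.53% and 4.83% in MC38.

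In MC38 the altered purine lay on the coding strand more often than on the transcribed strand for 5 of the 6 base changes. The coding strand held the G of 63.6% of its C>A changes (61.1 to 66.0, 991 of 1559, adjusted binomial p = 6.79e-26). The share was 65.0% for C>G (adjusted exact binomial p = 4.93e-10), 59.2% for C>T (adjusted p = 4.41e-05), 66.4% for T>A (adjusted p = 4.37e-10) and 60.9% for T>G (adjusted p = 0.00838). In B16BL6 the shares of C>A, C>G and C>T were 49.5%, 46.5% and 50.5%, with adjusted p of 0.563 or more, whereas T>A at 62.8%, T>C at 56.5% and T>G at 61.0% passed the test. The difference between the lines itself passed for C>A (odds ratio 1.78, 1.31 to 2.42, adjusted Fisher's exact p = 5.37e-04), C>G (2.14, 1.45 to 3.15, adjusted p = 3.74e-04) and C>T (1.42, 1.10 to 1.82, adjusted p = 0.0104). For T>A, T>C and T>G it did not pass (adjusted p of 0.270 or more). With at most 1 variant per gene and line, T>A and T>C in B16BL6 and T>G in MC38 no longer passed (60%, 57.5% and 56.2%).

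**Figure D2:**
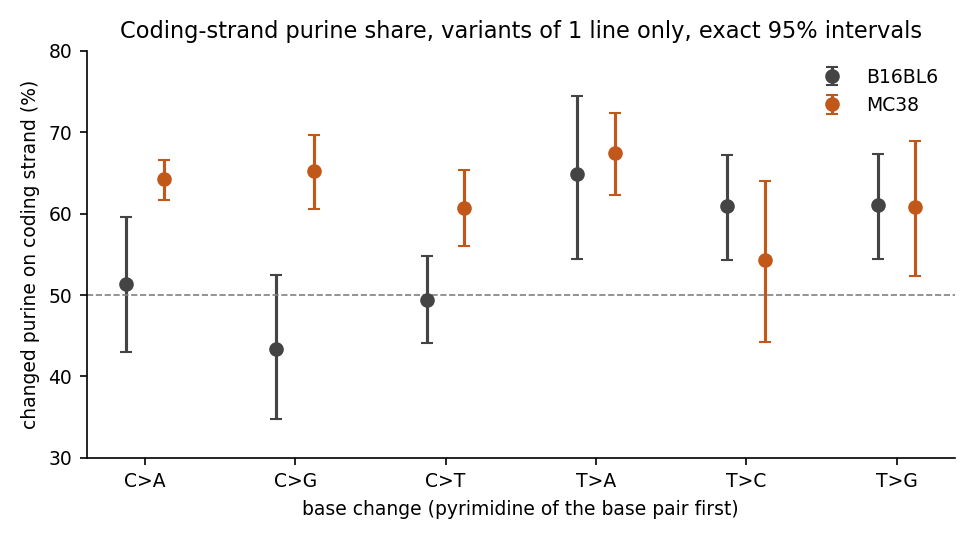
Percent of changes with the altered purine on the coding strand, by base change, among variants found in 1 line only; points are shares, bars exact 95% intervals, and the dashed line marks 50%. For C>A, C>G and C>T the MC38 shares are 64.2%, 65.2% and 60.7% and the B16BL6 shares 51.3%, 43.4% and 49.4%; the axis starts at 30%.

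Small insertions and deletions took a like share of both lists, and deletions were more common among those of MC38. They made up 2.66% of variants in B16BL6 (44 of 1654) and 2.33% in MC38 (81 of 3482), with an odds ratio of 0.871 (0.593 to 1.29, Fisher's exact p = 0.498). Deletions were 47.7% of these in B16BL6 and 70.4% in MC38 (odds ratio 2.58, 1.13 to 5.96, Fisher's exact p = 0.0198). Loss of a single C or G made up 37 of the 47 deletions of 1 base in MC38 and 7 of 14 in B16BL6 (Fisher's exact p = 0.0471, or 0.0523 in variants of 1 line only). The MC38 deletions included Ednrb A18fs, in the endothelin receptor of pigment cell precursors.

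Variants identical in both lines numbered 411, which is 24.8% of the B16BL6 list and 11.8% of the MC38 list. They crowded in a few genes. Mroh2a held 78, the mucin gene Muc4 57, the bilirubin-conjugating enzyme gene Ugt1a1 22 and the ribosome assembly gene Rrs1 18. In all, 309 lay in 23 genes with 3 or more each. A stretch of chromosome 1 from 88212021 to 88277442, with Ugt1a1, Ugt1a2, Mroh2a and the centromere chaperone gene Hjurp, held 126 of them. The first 5 genes in genome order with an identical protein-altering variant were Rrs1 (R113S), Obsl1 (T1764M), Sp140 (T148R), Ugt1a1 (S7N) and Ugt1a2 (T332M), with protein positions counted from the first residue of the annotated transcript. Of these, Obsl1 T1764M was homozygous in B16BL6 and in MC38. Of all shared variants, 301 were heterozygous and 97 homozygous in both lines. No position carried different alleles in the lines.

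The same genes were altered in both lines more often than gene numbers alone give. Protein-altering variants of both lines fell in 221 genes against 86.5 expected if the altered genes were drawn independently from 21896 (2.56-fold, Fisher's exact p = 5.86e-41). With shared variants and the genes crowded with them left out, an alternative chosen after seeing the data, 164 genes remained against 79.5 expected (2.06-fold, Fisher's exact p = 1.11e-19). The giant muscle gene Ttn led both lists of such variants, with 5 in B16BL6 and 13 in MC38. Gene size was not corrected for, and its part in the excess was not tested.

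Chromosome 11 took a larger share of the variants of MC38 than of B16BL6, where it fell short of its gene share. Among variants of 1 line only, it held 8.63% of those of MC38 (265) and 4.99% of those of B16BL6 (62), an odds ratio of 1.80 (1.35 to 2.43, adjusted Fisher's exact p = 5.20e-04). It was the only chromosome of 20 that passed between the lines in this set. Against its share of protein-coding genes, chromosome 11 stood at 0.670 in B16BL6 (adjusted binomial p = 0.00515). In MC38 it stood at 1.16, which did not pass (adjusted binomial p = 0.0587). With all variants 3 chromosomes differed between the lines, chromosome 11, chromosome 1 (odds ratio 0.712, adjusted Fisher's exact p = 0.00134) and chromosome 15 (odds ratio 1.66, adjusted Fisher's exact p = 0.0261). Without shared variants, chromosome 1 stood at 0.975 (adjusted Fisher's exact p = 0.851) and chromosome 15 at 1.46 (adjusted Fisher's exact p = 0.184). The X chromosome held 1.61% of the B16BL6-only and 1.82% of the MC38-only variants, 0.360 and 0.408 of its share of protein-coding genes (adjusted binomial p = 8.78e-07 and 9.10e-14).

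Homozygous calls were more frequent in MC38. Among variants of 1 line only, 340 of 3071 were homozygous in MC38 (11.1%, 9.98 to 12.2) and 48 of 1243 in B16BL6 (3.86%, 2.86 to 5.09), an odds ratio of 3.10 (Fisher's exact p = 1.38e-15). On the X chromosome 41 of 56 were homozygous in MC38 and 6 of 20 in B16BL6. The number of X copies in each line is unknown, and a variant on a lone copy could also be called homozygous. On the autosomes alone the odds ratio was 3.09 (Fisher's exact p = 5.52e-14). Among the autosomes of MC38, chromosome 15 had 26.8%, chromosome 3 22.2%, chromosome 6 19.9% and chromosome 4 17.6%, whereas chromosome 11 had 1.89%. In B16BL6 chromosome 9 had 11 of 57. With all variants the odds ratio was 1.53 (Fisher's exact p = 1.70e-05), and 97 shared variants were homozygous in both lines. The result was added after the lists were seen, in place of allele fractions.

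**Figure D3:**
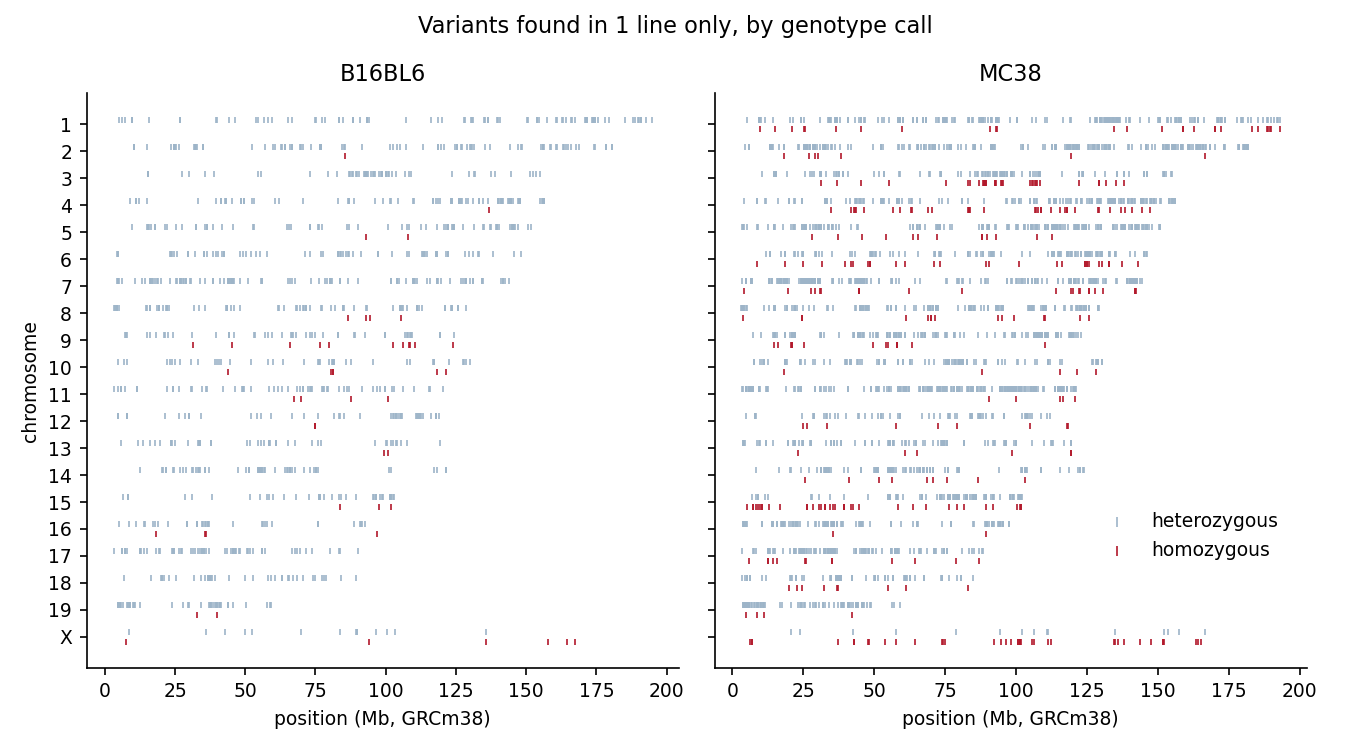
Position in Mb on each mouse chromosome (GRCm38) of the variants found in B16BL6 only (left) and MC38 only (right), with heterozygous calls in light blue and homozygous calls in red. MC38 has 340 homozygous calls, 41 of them on the X chromosome and 38 on chromosome 15, and B16BL6 has 48.

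Close variants of B16BL6 were for the most part shared variants. Within 10 bp of another lay 160 variants in B16BL6 (9.67%) and 256 in MC38 (7.35%), an odds ratio of 0.741 (Fisher's exact p = 0.00520). Among variants of 1 line only the counts were 37 (2.98%) and 128 (4.17%), so the direction turned (odds ratio 1.42, 0.970 to 2.12, Fisher's exact p = 0.0660). In that set the share was higher in MC38 within 5 bp (3.94% against 2.33%, odds ratio 1.72, 1.13 to 2.69, Fisher's exact p = 0.00990) and within 1000 bp (odds ratio 1.34, Fisher's exact p = 0.0171), and did not differ by the test within 50 bp (odds ratio 1.24, Fisher's exact p = 0.189). Runs of adjacent changed bases found in 1 line only numbered 9 in B16BL6 (4.12 to 17.1) and 32 in MC38 (21.9 to 45.2), of which 1 and 2 were longer than 2 bases. Of the 34 neighbouring pairs in the MC38 runs, 24 fell in a single codon, where the deposited annotation treats each base on its own, so that the stated amino acid change need not be that of the pair.

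The genes fixed from earlier descriptions of B16 sublines were the only list of 18 whose share of protein-altering variants differed between the lines. Of its 17 genes, 11 were altered in B16BL6 and 3 in MC38 (adjusted Fisher's exact p = 0.00702). The B16BL6 changes included Kif18b K739N in a mitotic kinesin, Pbk V145D in a mitotic kinase, Actn4 F835V in an actin cross-linker, Eef2 G795A in a translation factor and Rpl13a A24G in a ribosomal protein. Def8 R255G, Fzd7 G304A, Ppp1r7 L170P and Obsl1 T1764M were also on it, the last in both lines. Of the 10 genes from earlier descriptions of MC38, 7 were altered in MC38 and 0 in B16BL6 (adjusted Fisher's exact p = 0.565), among them Adpgk R304M, Aatf A500T, Cpne1 D302Y and Dpagt1 V213L. Both lists come from general knowledge of these lines, perhaps of related cell stocks, and are not independent evidence.

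Among signalling lists, no difference between the lines passed (adjusted Fisher's exact p of 0.668 or more). RTK, RAS and MAPK genes had 3 altered members of 30 in B16BL6 and 4 in MC38. These were Braf C264R, Fgfr2 L731H and Map2k2 A29G in B16BL6, and in MC38 included Braf W487C, homozygous at position 39643182 of chromosome 6 in exon 14, and Erbb4 with S433X and G586fs. PI3K and mTOR genes had 3 and 5 of 18. In B16BL6 these included Pik3r1 G71V and Pik3r2 L159M, in regulatory subunits of the lipid kinase. WNT genes had 1 each of 17, Apc Q1039X in B16BL6 and Gsk3b K297X in MC38, both in members of the complex that marks beta-catenin for destruction. TGF-beta and BMP genes had 0 and 4 of 12, with Acvr1 G43V and a homozygous Bmpr2 R321Q among the receptors of MC38. All 4 variants of that list fell in MC38, with an unadjusted Fisher's exact p of 0.315. In a list this small an excess in MC38 could not pass. The p53 and cell cycle list had 1 and 2 of 22, with Atm K92T in B16BL6 and Cdk6 C83S in MC38. Apoptosis genes had Casp9 L223V in B16BL6 and 0 of 20 in MC38.

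Chromatin and DNA repair lists had more altered genes in MC38, and their shares of the protein-altering variants did not differ between the lines by the test. Chromatin regulators were altered in 4 of 29 genes in B16BL6 and 12 in MC38 (adjusted Fisher's exact p = 0.751 between the lines). In simulated data an excess of 3-fold in this list was called in 43% of 100 runs, so a difference of that size can be missed. Against the share of all genes altered, and without regard to gene size, 2.72 were expected by number in MC38 (adjusted exact binomial p = 2.69e-05) and 1.21 in B16BL6 (adjusted exact binomial p = 0.0806). They included Smarca4 E1615X in the ATPase of a chromatin remodeller, Asxl1 G1227V and Chd4 A228S and Y1729F, and in B16BL6 Daxx S383Y, Kmt2b Q739K and Pbrm1 R1458Q. Double-strand break and nucleotide excision repair genes had 3 and 7 of 29. In MC38 these included Ercc6 W577X and S332C, in the factor that starts repair at stalled RNA polymerase. Whether both Ercc6 changes lie on the same copy is unknown. Prkdc G863X, Brca2 E2940K, Brip1 D1099E, Ercc2 S136R and Fanci V38L were also among the repair changes of MC38. In B16BL6 the repair changes were Brca2 K1997N, Ddb1 L438I and Fancd2 H1167D. Mismatch repair, base excision and proofreading polymerase genes had 0 and 3 of 18, with 4 variants, too few for an excess in MC38 to pass. Among these, chosen after the values were seen, Pold1 of MC38 carried a heterozygous R209L and a homozygous P110L, the latter annotated from 1 base of an adjacent pair in its codon. All of the named changes of Ercc6, Ercc2, Prkdc and Brca2 were heterozygous.

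No immune or lineage list differed between the lines by the test (adjusted Fisher's exact p of 0.668 or more). For interferon and for melanocyte genes, 0 variants in B16BL6 against 5 in MC38 gave an unadjusted Fisher's exact p of 0.334. No split of 5 variants leans further towards MC38, so lists this small could not show an excess there by the test. Antigen presentation genes had 1 and 2 of 20, a homozygous Nlrc5 D1275G in the class I transactivator of B16BL6 and, in MC38, Ciita P252T in the class II transactivator and Erap1 G33A and L166H in a peptide-trimming protease. Interferon signalling and checkpoint genes had 0 and 4 of 24. Melanocyte lineage genes had 0 of 18 in the melanoma B16BL6 and 5 in the carcinoma MC38, with truncations in Ednrb, Sox10 and Tyrp1 and against 1.69 expected by number (exact binomial p = 0.0611, adjusted over 36 tests). Intestinal epithelium genes had 0 and 2 of 18, with Cdh17 L458M, in an intestinal cadherin, in MC38.

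**Figure D4:**
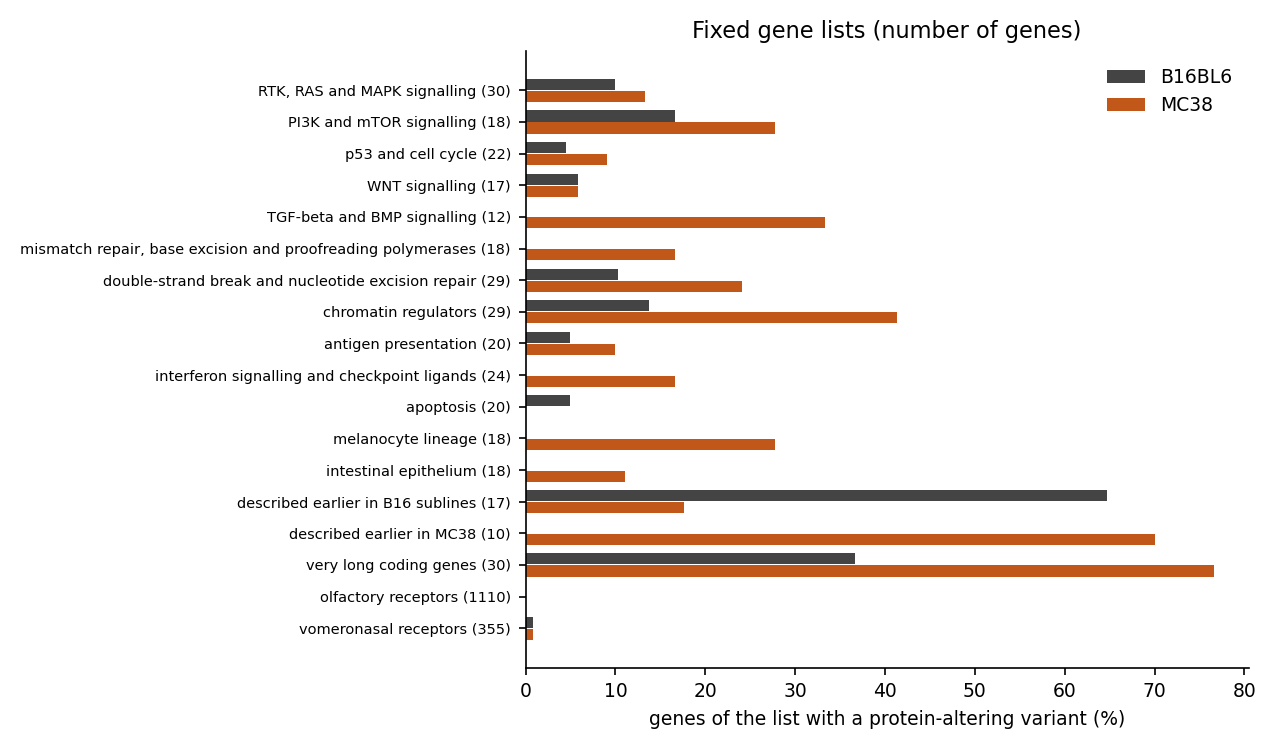
Percent of the genes of each fixed list with at least 1 protein-altering variant, in B16BL6 (grey) and MC38 (orange), with the number of genes in brackets. Very long coding genes stand at 11 and 23 of 30 genes, chromatin regulators at 4 and 12 of 29, and olfactory receptors at 1 and 0 of 1110.

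Very long coding genes and both receptor lists were the only lists that departed from gene numbers in both lines. Other lists departed in 1 line. In B16BL6 the list from earlier B16 descriptions had 11 of 17 against 0.710 expected (adjusted binomial p = 5.91e-11). In MC38 the list from earlier MC38 descriptions had 7 of 10 against 0.939 (adjusted binomial p = 2.69e-05), and chromatin regulators departed as given above. Both lists from earlier descriptions were made up of genes already described as altered in such lines, so their excess is not evidence. Very long coding genes were altered in 11 of 30 in B16BL6 and 23 of 30 in MC38, against 1.25 and 2.82 expected by number. That list was chosen by length, which gene numbers leave out, so its excess was to be foreseen. Olfactory receptor genes were altered in 1 of 1110 in B16BL6, Olfr819, and 0 in MC38, against 46.3 and 104 expected by number (adjusted binomial p = 4.01e-18 and 1.64e-46). Vomeronasal receptor genes were altered in 3 of 355 in each line, against 14.8 and 33.3. Which regions the capture pool and the filters on calls covered is not given in the sources used here. By number of protein-altering variants, Muc4 (43), Mroh2a (38), Rrs1 (23), Zfp982 (16) and Ugt1a1 (14) led in B16BL6. Muc4 (47), Mroh2a (36), Rrs1 (17), Ugt1a1 (14) and Ttn (13) led in MC38.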

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

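The tests of base composition, of guanine oxidation and of each base change taken alone in the gene sets were chosen after the strand shares had been seen.

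The strand of the altered purine differed between the lines for C>A (odds ratio 1.78), C>G (2.14) and C>T (1.42), each by a test of the difference itself.

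Base composition of the coding strand would give both lines the same C>A share, and the Fisher's exact p of 0.00248 in variants of 1 line only argues against it as the whole cause for C>A. Oxidation of guanine during library preparation would strike both gene strands alike, whereas the lower 95% limit of the MC38 C>A share was 61.7%, and C>A also made up 52.6% of homozygous MC38-only changes. Repair tied to transcription, a biological explanation, predicted a lower purine share in silent genes, but only 4 MC38-only changes fell in olfactory and vomeronasal receptor genes, too few to decide. Gene sets were drawn up by symbol after the strand shares were known, but before the shares in these sets were computed. Over all changes they met the prediction. In broadly used genes 84.3% of MC38-only changes (77.6 to 89.7, 129 of 153) had the purine on the coding strand. In genes of nerve, muscle, cilia and receptors 50.7% did (43.7 to 57.8, 104 of 205, Fisher's exact p = 1.97e-11). The 153 changes lay in 121 genes and the 205 in 125. Changes of the same gene were taken as independent, and the comparison was not run with 1 variant per gene, so its p values may be too small. Taken alone, C>A, T>A and C>T passed (Fisher's exact p of 1.79e-07, 0.0221 and 0.0467, adjusted over the 6 base changes). T>C, with 3 of 4 and 1 of 10 (adjusted Fisher's exact p = 0.0614), and T>G, with 7 of 8 and 2 of 6 (0.109), did not pass. C>G taken alone did not follow, with 12 of 20 and 17 of 25 (Fisher's exact p = 0.755), and stays open. In B16BL6 the shares over all changes were 54.9% and 62.0% (Fisher's exact p = 0.496), and the odds ratios of the lines, 5.20 and 0.749, differed (likelihood ratio p = 4.92e-06), which is consistent with purine damage in MC38 that transcription-linked repair removes, a hypothesis without measured expression behind it.

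Variants without a gene annotation, which no comparison by gene used, numbered 42 in B16BL6 and 49 in MC38, and 33 were identical in both lines.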

How the results depend on the processing

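The alternative that leaves out shared variants and the genes with 3 or more of them, and all alternatives of the homozygous share, were chosen after seeing the data. Of 275 alternative values, 240 were kept. For tested results this means the same direction and side of the threshold, and for counts without a test a value within a set factor of the main count. The MC38 over B16BL6 ratio of protein-altering variants ranged from 2.10 to 2.52 and the C>A odds ratio from 6.07 to 7.33. The odds ratio of nonsynonymous to synonymous changes, never past the threshold, turned to 0.977 without shared variants and 0.990 without shared variants and their genes. B16BL6 strand shares close to 50% crossed it, none past the threshold: C>A stood at 51.3% without shared variants, 50.3% without close variants, 50% without large families, 50.4% at 1 variant per gene and 52.1% without shared variants and their genes, and C>T at 49.4%, 49.7% without families, 49.0% at 1 per gene and 48.6% without shared genes. MC38 T>C reached 50% without close variants, and the T>G strand odds ratio 1.02 without families. At 1 variant per gene, which leaves fewer variants, T>A (60%) and T>C (57.5%) in B16BL6 and T>G (56.2%) in MC38 missed the threshold, shared variants fell to 97, and the antigen presentation and very long gene lists turned to -0.0110 and -0.160 points, MC38 minus B16BL6.

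The number of chromosomes that differed was 1 without shared variants, at 1 variant per gene and without shared genes; against gene numbers it was 7 in B16BL6 and 8 in MC38. Variants within 10 bp of another numbered 37 and 128 (B16BL6, MC38) without shared variants, 10 and 7 at 1 per gene and 22 and 122 without shared genes. A 5 bp window gave 104 in B16BL6, and a 50 bp window 318 and 423. Against gene numbers, adjusted over both lines, 4 and 5 gene lists passed. The cause of these changes was not tested. Alternatives on depth and allele fraction were not run, since the lists hold neither, and no value was had for shared variants without themselves, close variants without themselves or receptor lists without their families. No paired analysis was possible because each line has 1 library.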

Other observations

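The tests on crowded shared variants and the shuffles with neighbours or genes reduced to 1 variant were chosen after the results had been seen.

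Some altered genes outside the naming rule were chosen after their values were seen. MC38 carried a heterozygous Trp53 G242V in the p53 tumour suppressor, Smad4 G351R and Smad2 V289L in the TGF-beta signal transducers, and 2 homozygous changes, D679Y and Q1902H, in the X-linked mediator gene Med12. Its interferon pathway changes were Jak1 G654V and M640I, Irf2 R110L, Irf9 V97F and Ifih1 Q248P. Mtor held H2401L and V2403L. B16BL6 also carried Tubb3 G402A, Tnpo3 G504A and Trrap K2783R.

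Types of adjacent pairs, picked after they were seen, were not tested between the lines. Of 34 adjacent pairs found in MC38 only, 5 were CC>AT, 5 CG>AT and 4 CC>AA, and 33 had the same genotype at both bases. In B16BL6, AG>GA was seen in 2 of 10 and CC>TT, the pair known from ultraviolet light, in 1.

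Shared variants that crowd within 1000 bp of each other were heterozygous in both lines in 79.5% (74.9 to 83.7, 272 of 342), which is consistent with reads from near-identical gene copies. Strain differences from the reference would be homozygous in both lines, and 17.0% (13.1 to 21.4) were, which argues against them as the whole cause but not for each gene: 11 of 22 in Ugt1a1 and 23 of 78 in Mroh2a were homozygous in both, against 0 of 18 in Rrs1 and 0 of 15 in Thap1. MC38 DNA in the B16BL6 library would carry the MC38-only C>A share, 50.6%, and the variants heterozygous in both had 14.0% (10.2 to 18.5). B16BL6 DNA in the MC38 library would carry the B16BL6-only T>G share, 19.7% (17.5 to 22.1), and the crowded variants had 9.25% (5.20 to 14.2, resampled over 50 groups of neighbours with the level adjusted over 6 base changes). The intervals of 79.5%, 17.0% and 14.0% were not resampled. They took each variant as independent, which neighbours need not be, so they may be too narrow. Of the 69 shared variants standing alone, 56.5% (44.0 to 68.4) were homozygous in both lines, so strain differences stay open there, and no biological explanation was tested.

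Homozygous MC38-only calls on autosomes had 59 neighbour pairs against a mean of 41.8 in 10000 shuffles within chromosomes (permutation p = 0.0012); with 1 variant per group within 1000 bp p was 0.0103, and with 1 per gene as well 0.0164, which argues against scattered genotyping error. Loss of one copy over segments predicted 10 Mb windows with at least 80% homozygous variants, and there were 0 among 208 windows with 5 or more variants. The shuffles had a median of 0 as well, so the count had no room to be lower and the test does not decide. The highest window, on chromosome 15 from 30000000 to 40000000, had 10 of 13 homozygous (76.9%). The windows next in rank adjoined it, from 0 to 30000000 on the same chromosome, with 6 of 10, 4 of 6 and 3 of 5. This stretch was seen by ranking and was not tested. Copy number was not analysed here, so loss and copying of segments stay open, as does whatever set the calls.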
